A study of Arabidopsis thaliana with 27 samples.

How the data were processed

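The series holds 27 Affymetrix ATH1 arrays of total RNA, labelled with biotin, from laser-dissected Arabidopsis embryo tissues. Each deposited value is a probe set intensity on a linear scale; the values were made with MAS5, per the submitters' processing notes, and the version and settings are not given in the sources used here. The deposited intensities average about 100 on every array after trimming 2% of values at each end, so they were taken as already scaled by the authors. Values of 18 arrays carry 1 decimal and those of the 9 torpedo apical, basal and meristem arrays are unrounded. The scanner files and probe-level data were not analysed here, so background correction and summarisation could not be varied.

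Groups were taken from the titles. 25 arrays fell into 9 groups of 2 or 3 arrays. The remaining 2 arrays, whose title and tissue description contradict each other, stayed out of every comparison and were added by title and by tissue description as alternatives. The labels do not say how captures relate to plants or embryos or how the regions were chosen, so arrays were treated as the replicates.

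A pseudocount of 10.0, which is 10% of the trimmed mean, was added and values were taken as log2, with no further normalization. A log2 difference is on this scale and understates the change of dim probe sets. The 64 control probe sets were left out, and a probe set was tested if its value reached 50.0 on at least 2 of the 25 arrays, which left 20890. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, 1 mean per group, and eBayes with an intensity trend) over all 25 arrays, so that the groups share an estimate of the spread. Tests were 2-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Errors beside signals are SDs over arrays, and errors beside log2 differences are standard errors of the fit.

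15 gene lists, the comparisons, the tests, the rule for named genes and the first set of other settings were chosen before the data were examined. 10 further lists were built from the names in the gene table before differences were computed, because few genes of the first lists carry a name there. Lists were tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison.

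Probe sets were named from a table of probe sets and genes for the platform, with gene identifiers updated through NCBI RefSeq names of assembly TAIR10.1 (13436 identifiers matched). Of the probe sets, 13513 had 1 gene, 503 had several and 8730 had none, and probe sets with several genes or none were not named. A probe set without a name here is not a probe set without a gene. No genome build is named for the values, so no coordinates are given.

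By the rule for named genes, each comparison names up to 8 probe sets with the largest rise and 8 with the largest fall among those past the threshold whose groups do not overlap and that map to 1 gene with a symbol, and up to 3 members of each list past the threshold. A set of patterning genes that the rule also asks for had no single-gene name in the table and was not used here. The rule's word symbol was read to include locus codes after the calls had been seen, since 11933 of the single-gene probe sets carry only such a code. List members that did not pass, the genes called with array weights, and the genes drawn in the plot of signals per array were chosen after their values were seen.

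Before use, the fit was tested on simulated data with the spread of the real arrays and 200 changed probe sets among 20890 in each of 10 draws. For torpedo apical against basal it recovered 57.0% of log2 changes of 4, 2.06% of changes of 2 and 0% of changes of 1, and 0.512% of its calls were false. For globular apical against basal it recovered 62.5%, 5.28% and 0.161%, with 1.05% false calls. For heart against globular it recovered 89.8%, 28.5% and 1.32%, with 9.11% false calls. The simulated noise was independent between probe sets, whereas single real arrays deviated over many probe sets together. The false shares also depend on the number and size of the changes planted. They therefore do not give the false share of the real calls.

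The other settings fixed in this way were quantile normalization, median centring, other pseudocounts and filters, no intensity trend, array weights, a fit on only the groups compared, the replicate number as a block and leaving out each array in turn. Added after seeing the data were fits without arrays of low correlation (median under 0.4) or of high hybridization controls (over 4 times the median), those controls as a covariate, and 2 other groupings of the torpedo captures. Other scaling shifts the median of all probe sets: the median log2 difference was -0.06 for globular, 0.29 for heart, -0.35 for torpedo cotyledon against root, -0.14 for torpedo apical against basal, 0.20 for meristem, -0.23 for heart against globular, 0.24 for torpedo against heart, -0.42 for apical against cotyledon, -0.52 for basal against root, 0.51 for torpedo root against heart root, 0.47 for meristem against apical and basal and -0.24 for apical and basal against heart, and median centring removes it. The ratio of 3' to 5' probe sets of actin and of GAPDH was taken from the control probe sets of each array. Figures were drawn with matplotlib 3.10.9.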

Results

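RNA of laser-dissected tissues from Arabidopsis thaliana Col-0 embryos was hybridised to 27 Affymetrix ATH1 arrays, each measuring 22810 probe sets. The captures covered the globular stage (apical and basal parts), the heart stage (cotyledon and root poles) and the torpedo stage (cotyledon, root, apical part, basal part and meristem). 7 of the 9 groups held 3 arrays each. Torpedo cotyledon and torpedo root held 2 arrays each, because the title and the tissue description of 2 further arrays named opposite tissues, and these 2 arrays entered no comparison. The labels do not tie captures to plants or embryos, so p-values measure only the spread between these arrays, which may be technical. Globular apical 1 carries a different growth description from the other arrays. The small number of arrays per group limits the precision of every difference below.

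The arrays differed widely in quality. The geometric mean of the 18 hybridization-control probe sets ran from 379.8 on torpedo apical 5 to 71930 on torpedo root 3, a 189-fold range around a median of 1590. The median correlation of an array with the other arrays ran from 0.255 on torpedo root 3 to 0.593. 4 arrays with a group lay below 0.4, namely torpedo root 3, heart cotyledon 2 (0.294), torpedo root 1 (0.301) and torpedo meristem 1 (0.319). Controls over 4 times the median were seen on torpedo root 3, torpedo cotyledon 3 (31215), torpedo root 1 (9406) and globular apical 3 (8388). Torpedo apical arrays correlated with each other at 0.854 to 0.878, whereas the 2 torpedo root arrays correlated at 0.161. Torpedo basal arrays correlated at 0.50 to 0.82; basal 5 stood apart from basal 4 and 6, with a mean correlation of 0.502 within its group against 0.66 and 0.662, its highest correlation elsewhere with torpedo meristem 2 (0.598), and an array weight of 0.382. The log2 ratio of 3' to 5' probe sets of actin was 2.39 to 5.07 on torpedo apical and basal arrays, -1.55 to 2.58 on meristem arrays and -1.80 to 1.85 on heart arrays. It was -1.75 to 0.51 on globular arrays, 1.08 and 1.80 on torpedo cotyledon arrays and -1.40 and -1.18 on torpedo root arrays. The same ratio of GAPDH overlapped, at 5.47 to 7.62 on apical and basal and 5.16 to 8.02 on heart arrays, and was -2.61 on torpedo root 1.

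**Figure D1:**
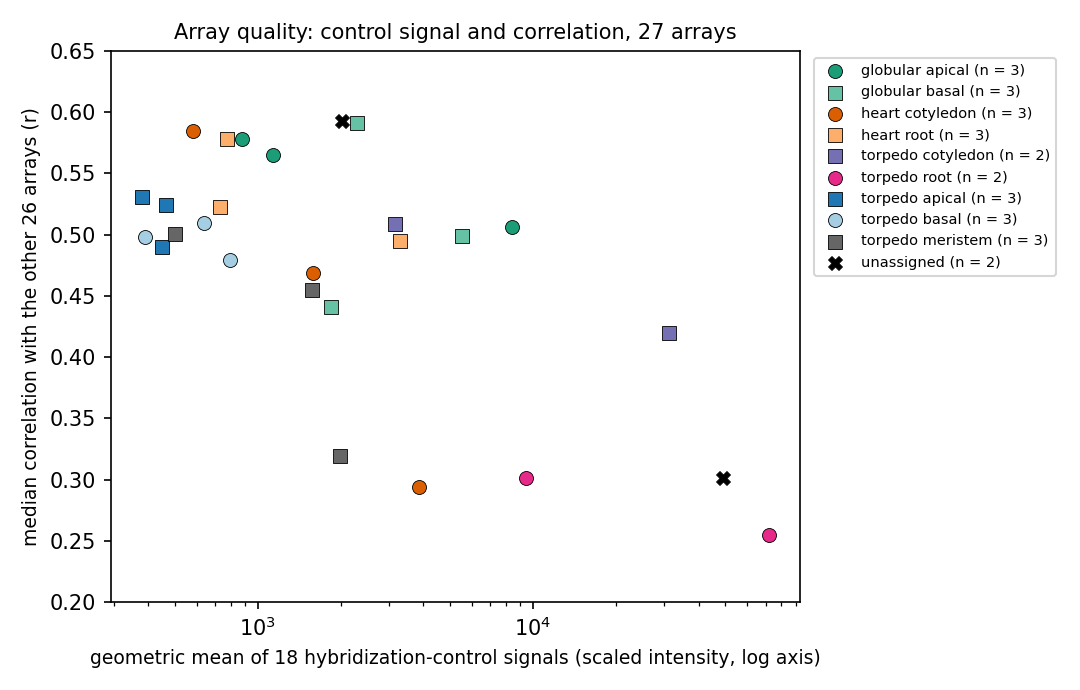
Median correlation of each of the 27 arrays with the other 26 (vertical axis, Pearson's r) against the geometric mean of 18 hybridization-control signals (horizontal axis, scaled intensity, logarithmic), with 1 point per array, coloured by group. Torpedo root 3 has both the highest control signal (71930) and the lowest correlation (0.255), while the torpedo apical arrays sit between 379.8 and 462.7 on the control axis.

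The torpedo apical and basal captures address how the upper and lower parts of the embryo differ once cotyledons have grown out. NGA1, a B3-domain transcription factor of lateral organ growth, had a signal of 199 ± 8.60 (SD, n = 3) in apical and 7.81 ± 5.17 (n = 3) in basal captures, a log2 difference of 3.59 (SE 0.73). GH3.3, which conjugates amino acids to auxin, was at 1035 ± 620 apically and 47.2 ± 64.0 basally, a log2 difference of 4.75 (SE 0.93). AT5G44680 was at 289 ± 132 apically and 3.04 ± 1.04 basally, a difference of 4.44 (SE 0.57). The opposite pattern held for SDT, a spermidine acyltransferase gene, with 12.5 ± 8.80 apically and 608 ± 215 basally, a difference of -4.82 (SE 0.72). AT1G71695, a class III peroxidase gene (4.57), and AT3G51660 (3.61) were also higher apically, and AT2G26520 (-4.58), AT5G35940 (-4.14) and AT2G31390 (-3.43) were higher basally.

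By limma, 19 of 20890 probe sets passed an adjusted p of 0.05 between torpedo apical and basal. Of these 14 were higher and 5 lower in apical, and 9 carried a single gene name. At an unadjusted p under 0.05 there were 817, where chance alone gives 1044. Adjusted p-values were 0.000593 for AT5G44680, 0.0023 for SDT, and 0.0485 for both NGA1 and GH3.3. A planned fit that weights arrays by their reproducibility called 196 probe sets, 101 higher and 95 lower, including all 19. The count was 9 after quantile normalization, 5 with a pseudocount of 1% and 7 without the intensity trend. It was 3, 5 and 6 without torpedo apical 4, 5 or 6, and 7 and 5 without torpedo basal 4 or 6. With each of the 6 arrays left out in turn AT5G44680 always passed, SDT passed except without torpedo apical 4 (-4.44, adjusted p = 0.0601), and NGA1, AT1G71695 and AT2G31390 passed in none; NGA1 then had adjusted p-values of 0.0945 to 0.327. GH3.3 passed only without torpedo basal 5, and its adjusted p without another array was 0.127 to 0.337. Over all 21 alternative runs AT5G44680 passed in 21, SDT in 20, AT5G35940 in 14, GH3.3 in 10, NGA1 in 8, AT1G71695 and AT2G31390 in 7, AT3G51660 in 6 and AT2G26520 in 4.

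Gene lists for organ polarity and for the root pole separated the same captures in opposite directions. Of 19 cotyledon and leaf polarity genes listed 4 were measured, and of 21 root pole genes 2. A wider list of 33 measured polarity, meristem and patterning genes, which holds the measured genes of both, was not called here. All 4 measured cotyledon and leaf polarity genes had positive differences: YAB3, an abaxial identity factor (3.55, SE 0.89, adjusted p = 0.192), PHV (1.94), JAG (1.17) and YAB5 (0.59), although YAB5 was at -0.19 without torpedo basal 6. The list as a whole rose, with a median of 1.55 and a camera adjusted p of 0.000145, or adjusted p = 0.0133 with an estimated correlation. 1 of its 4 members, YAB3, passed when adjusted over the list alone, and 0 passed over all probe sets. Both measured root pole genes had negative differences, the embryo and root stem cell factor BBM at -4.17 (signal 2.34 ± 1.47 apically, 279 ± 233 basally) and the ground tissue factor JKD at -2.35. This list fell, with a median of -3.26 and an adjusted p of 0.00138, or adjusted p = 0.0157 with an estimated correlation, and both members passed adjusted over the list alone. YUC4, an auxin synthesis gene, differed by 2.82 (SE 0.83, adjusted p = 0.445) and passed adjusted over its list alone. That auxin list holds only 3 measured genes of 31 and was not called as a list here. With array weights YAB3 reached an adjusted p of 0.00221 (0.0022 to 0.878 over 21 alternatives), YUC4 0.0134 (0.0134 to 1.00) and BBM 0.0188 (0.0188 to 1.00). Array weights was the only 1 of the 21 alternatives in which any of these genes passed over all probe sets. Nuclear photosynthesis genes (median 0.54, adjusted p = 0.0116) and cell division genes (0.20, 0.0463) rose by camera, at adjusted p = 0.196 and adjusted p = 0.311 with an estimated correlation. Both calls ended without torpedo basal 5 (adjusted p = 0.435 and 0.878) or without torpedo apical 4 (0.0627 and 0.0765), and over 23 alternative runs they held in 18 and 11. Torpedo basal 5 is the basal array that stood apart.

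**Figure D2:**
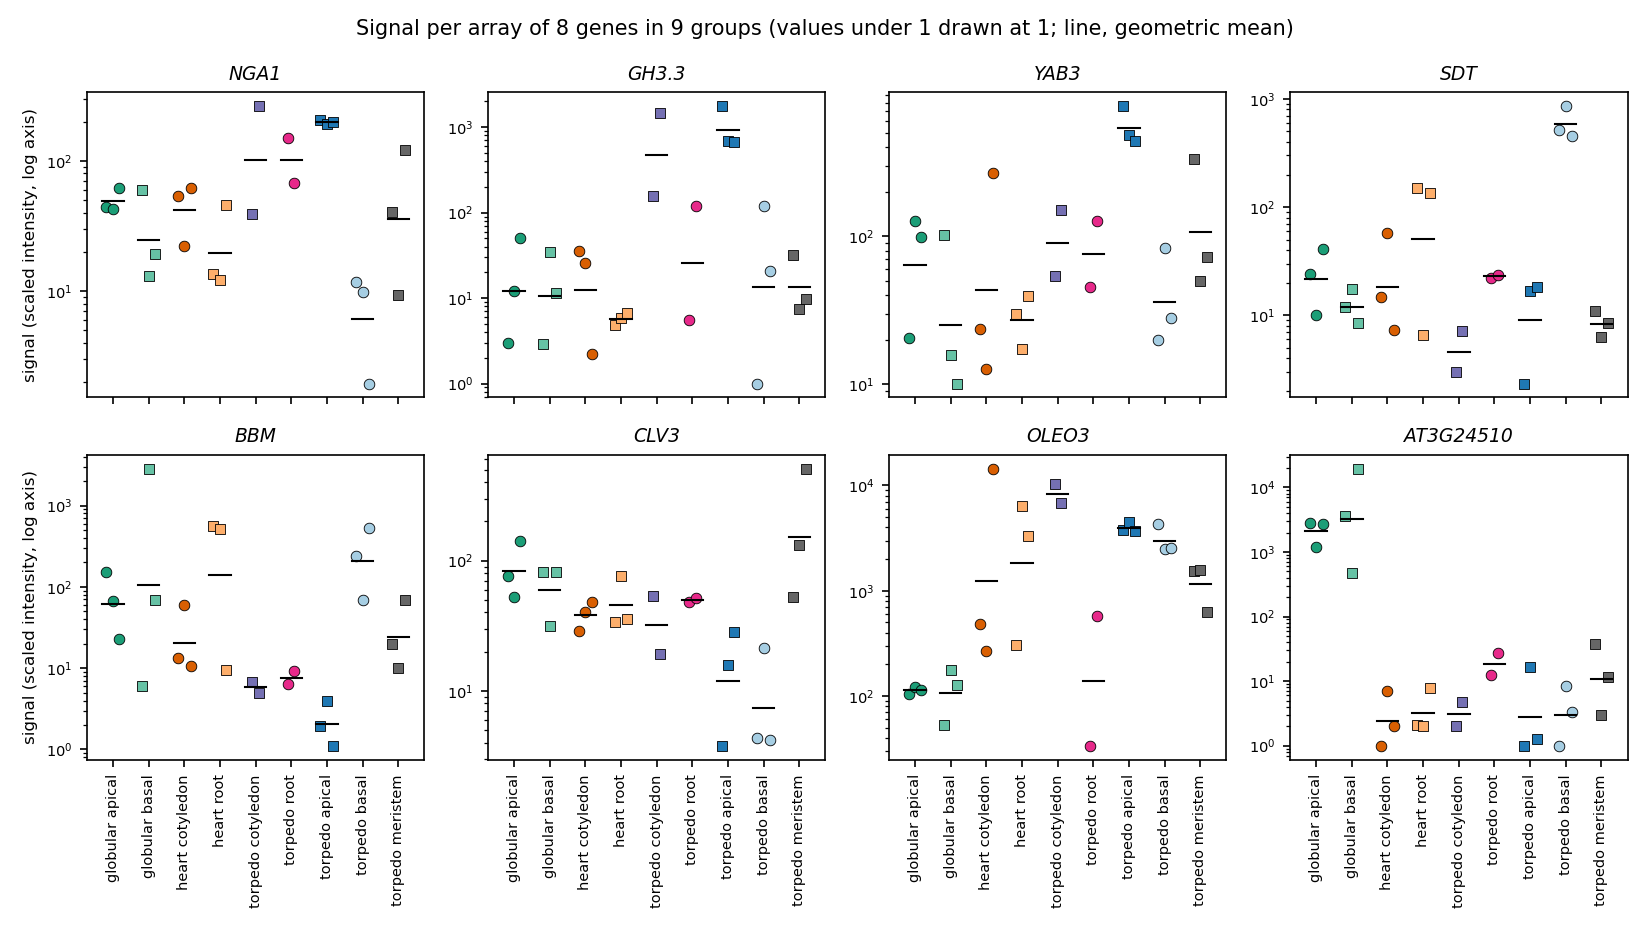
Signal of 8 genes on each of 25 arrays in 9 groups (vertical axis, scaled intensity, logarithmic), with 1 point per array, a line at the geometric mean, and values under 1 drawn at 1. NGA1, GH3.3 and YAB3 are high in torpedo apical, SDT is near 608 in torpedo basal, and AT3G24510 is high on the globular arrays only (466 or above on each).

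At the globular stage no gene separated the apical and basal captures past the threshold. BBM had a signal of 81.4 ± 66.6 (SD, n = 3) in apical and 975 ± 1625 (n = 3) in basal captures, a log2 difference of -1.04 (SE 1.28), and YAB3 differed by 0.99 (SE 0.89). Cytosolic ribosomal protein genes were lower in apical captures, with 50 of 63 members below 0, a median of -0.68 and a camera adjusted p of 0.0214, or adjusted p = 0.953 with an estimated correlation. That call also ended without globular basal 1 (-0.54, adjusted p = 0.471), without globular apical 2 (-0.37, adjusted p = 0.663) and after quantile normalization (-0.31, adjusted p = 0.332). limma called 0 of 20890 probe sets, with a smallest adjusted p of 0.423, and array weights also called 0. At an unadjusted p under 0.05, 561 probe sets were found where chance alone gives 1044, and array weights gave 1086. The main fit shares its spread with groups whose arrays agreed less, so it may overstate the error here. The count was 2 without globular apical 2 and 1 without globular basal 2.

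In the heart stage embryo, JKD had a signal of 239 ± 240 (SD, n = 3) at the root pole against 14.6 ± 16.6 (n = 3) at the cotyledon pole, a log2 difference of -2.98 (SE 0.87, adjusted p = 0.461). BBM was at 359 ± 304 in root and 28.1 ± 28.0 in cotyledon captures, a difference of -2.47 (SE 1.28, adjusted p = 0.968). These 2 genes are the measured part of the root pole list, which fell in cotyledon relative to root captures with a median of -2.72 and a camera adjusted p of 0.000758, or adjusted p = 0.0232 with an estimated correlation. JKD passed adjusted over the list alone. Cytosolic ribosomal protein genes were lower at the cotyledon pole (median -1.04, adjusted p = 2.16e-10, and adjusted p = 0.551 with an estimated correlation), but their median was 0.0139 without heart cotyledon 2, whose correlation with the other arrays was 0.294. The photosynthesis list (median -0.34, adjusted p = 0.0399) and the wider nuclear photosynthesis list (median 0.02, mean -0.37, adjusted p = 0.0128) were called lower, at adjusted p = 0.551 and adjusted p = 0.308 with an estimated correlation. Both were at adjusted p = 0.994 without heart cotyledon 2, where the photosynthesis median was 0.30, at 0.226 without heart root 2, and at 0.51 and 0.172 without heart root 3; the former was at 0.0639 without heart cotyledon 1. Over 23 alternative runs these calls held in 8 and 16.

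2 probe sets passed limma's threshold between the heart poles, 1 higher (5.70) and 1 lower (-5.65) in cotyledon, and neither has a gene name in the probe table. They lie outside the rule for named genes and are given because the count is small. At an unadjusted p under 0.05, 1112 probe sets were found. The count was 50 without heart cotyledon 1, 5 without heart cotyledon 2, 0 without heart cotyledon 3, and 8, 5 and 6 without heart root 1, 2 or 3.

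AT3G62920 was higher in torpedo cotyledon than in torpedo root captures, with signals of 4117 ± 4726 (SD, n = 2) and 12.1 ± 4.101 (n = 2), a log2 difference of 6.79 (SE 0.99, adjusted p = 0.00549). All 9 measured photosynthesis genes had positive differences, including the light-harvesting genes LHCB4.1 (4.78, SE 1.38) and LHCB4.2 (4.61, SE 1.5003) and the photosystem II subunit gene PSBW (5.29, SE 1.69). These 3 genes passed adjusted over the list alone and 0 passed over all probe sets. By camera the photosynthesis list (median 1.96, adjusted p = 2.12e-06), the nuclear photosynthesis list (0.73, 2.12e-06) and cytosolic ribosomal protein genes (2.95, 2.38e-29) rose, at adjusted p = 0.0377, 0.0227 and 0.0377 with an estimated correlation. Plastid-encoded genes were called higher (median 0.08, adjusted p = 0.00112), at adjusted p = 0.0937 with an estimated correlation, 0.062 without torpedo cotyledon 1 and 0.0777 without torpedo root 1, and with the 2 contradicting arrays added by tissue description their median turned to -0.44 (adjusted p = 0.747). The photosynthesis median was 0.72 without torpedo cotyledon 3, and the ribosomal median 1.36 without torpedo root 1 and 1.46 with those 2 arrays added. The torpedo root arrays had correlations of 0.301 and 0.255 and controls of 9406 and 71930. The actin 3' to 5' ratio was 1.08 and 1.80 on cotyledon and -1.40 and -1.18 on root arrays, and that of GAPDH was -2.61 on root 1. These values accompany every list in this comparison. The root pole list, BBM and JKD, was not among the lists called here. From heart to torpedo its difference between the poles changed by a median of 3.11 (2.13 to 3.81 over 25 alternative runs). By camera with an estimated correlation that change was at adjusted p = 0.0760. Whether the difference of these 2 genes between the poles changed from heart to torpedo is therefore not settled. The torpedo root arrays also agreed poorly, at a correlation of 0.161 with each other. limma called 2 probe sets, both higher in cotyledon; the count was 86 without torpedo cotyledon 3, and 0 without torpedo root 1, without torpedo root 3 or with array weights. AT3G62920 lost its call without torpedo cotyledon 1 (5.16, adjusted p = 0.211), root 1 (0.102) or root 3 (0.0935), and over 17 alternative runs it passed in 10 (adjusted p up to 0.703). With the contradicting arrays added by tissue description, the nuclear photosynthesis list was at 0.10 (adjusted p = 0.272) and lost its call. In the main limma fit 845 probe sets were higher and 1608 lower in cotyledon captures at an unadjusted p under 0.05.

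The meristem captures showed AT5G03350, a legume-lectin-like gene, at 1819 ± 1209 (SD, n = 3), against 114 ± 5.83 in torpedo apical (n = 3), 26.4 ± 17.1 in basal (n = 3), 15.1 ± 11.6 in cotyledon (n = 2) and 21.1 ± 14.9 in root captures (n = 2). Its log2 difference from the mean of the 4 other torpedo tissues was 5.09 (SE 0.69, adjusted p = 0.00165). CLV3, the signal peptide gene of shoot stem cells, was at 232 ± 244 in meristem, 15.9 ± 12.2 in apical and 9.99 ± 9.90 in basal captures. Its difference from the 4 other tissues was 2.35 (SE 0.57, adjusted p = 0.126), less than the 2.99 from apical and basal captures alone. CLV3 thus averaged higher, on the log2 scale, in cotyledon and root than in apical and basal captures. LAS, a regulator of axillary meristems, differed from the 4 tissues by 1.44 (SE 0.62). These 2 genes form the measured shoot meristem list, which rose with a median of 1.90 and a camera adjusted p of 0.00922, or adjusted p = 0.114 with an estimated correlation. Both passed adjusted over the list alone. Nuclear photosynthesis genes (median -0.46, adjusted p = 0.00235) and cytosolic ribosomal protein genes (-0.75, 2.56e-07) fell, at adjusted p = 0.125 and adjusted p = 0.562 with an estimated correlation. Without torpedo meristem 3 the shoot meristem list was at 1.44 (adjusted p = 0.265) and the nuclear photosynthesis list at -0.28 (0.321); without torpedo meristem 1 the nuclear photosynthesis and ribosomal lists were at -0.28 and -0.02 (both 0.065). The nuclear photosynthesis call also ended after quantile normalization (-0.43, adjusted p = 0.0948).

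AT5G03350 was the single probe set past limma's threshold against the 4 tissues, and it stayed past it in all 26 alternative runs. Against apical and basal captures alone, a comparison added after seeing the data because these values were deposited in the same form, 35 probe sets passed, 24 higher and 11 lower in meristem. This balance turned with the setting: 8 were higher and 24 lower after median centring, 12 and 52 with only these groups in the fit, 6 and 6 after quantile normalization, and 485 and 87 with array weights. The actin 3' to 5' ratio was -1.55, 2.58 and -0.81 on the meristem arrays and 2.39 to 5.07 on the apical and basal arrays. AT5G03350 (4.45), AT3G53310 (4.01) and CLV3 (2.99, SE 0.61, adjusted p = 0.0431) were higher, and AT1G29270 (-5.40), AT5G01870 (-5.11) and SEC, an O-linked N-acetylglucosamine transferase gene (-3.46), were lower. Plastid-encoded (median -0.55) and nuclear photosynthesis genes (-0.61) fell, both at adjusted p = 2.84e-07 and adjusted p = 0.0115 with an estimated correlation. The count against 4 tissues was 56 without torpedo basal 5, 16, 4 and 3 without torpedo meristem 3, 2 or 1, 3 without torpedo cotyledon 3, and 2 without torpedo root 1 or 3. Against apical and basal it was 0 without torpedo basal 4, basal 6 or apical 4, 8 and 6 without apical 5 or 6, 6 and 215 without meristem 1 or 2, and 1409 without basal 5, and CLV3 lost its call in 11 of 24 alternative runs (adjusted p of 0.00815 to 0.129 over all of them). 6 of these left out torpedo basal 4, basal 6, apical 4, 5 or 6, or meristem 3 (2.17, adjusted p = 0.129), and the others were quantile normalization, median centring, only these groups in the fit, no arrays of high controls and the controls as a covariate. Over the same 24 runs AT5G01870 lost its call in 12 (adjusted p up to 0.203), SEC in 10, AT1G29270 in 8, AT3G53310 in 4 and AT5G03350 in 3.

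From the globular to the heart stage AT3G24510 fell from 2227 ± 902 (SD, n = 3) in apical and 7896 ± 10262 (n = 3) in basal captures to 3.2 ± 3.36 and 3.97 ± 3.32 in heart cotyledon and root captures (n = 3 each). Its log2 difference was -7.61 (SE 0.61, adjusted p = 2.71e-08). AT2G30810, a gene of the gibberellin-regulated GASA family, fell from 2145 ± 1214 and 3058 ± 1437 to 64.5 ± 62.7 and 59.2 ± 28.5, a difference of -5.25 (SE 0.54, adjusted p = 2.48e-06). AT5G06190 (-5.61), AT1G09370 (-4.74) and LCR24, of the family of small cysteine-rich proteins (-3.95), also fell, although their arrays overlapped between stages, so that they lie outside the rule for named genes here. In heart cotyledon against globular apical captures these 3 genes fell with no overlap, by -6.28, -5.38 and -4.997. In heart root against globular basal captures none of the 3 passed the threshold. The comparisons by pole were set beforehand as counts, so naming these genes there was chosen after the result was seen.

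Photosynthesis genes were higher at the heart stage as lists. PSAE-1, a photosystem I subunit gene, differed by 3.79 (SE 0.84, adjusted p = 0.0932), LHCB4.1 by 3.66 (SE 0.80, adjusted p = 0.0838) and LHCB4.2 by 2.96 (SE 0.87, adjusted p = 0.332). These 3 of 9 photosynthesis genes passed adjusted over the list alone and 0 passed over all probe sets. The list rose (median 0.52, adjusted p = 1.10e-06, and adjusted p = 0.0259 with an estimated correlation), as did the wider nuclear photosynthesis list (0.64, 7.85e-10, and adjusted p = 0.00224 with an estimated correlation). OLEO3, an oil body protein gene, was at 113 ± 8.73 and 119 ± 63.0 in globular captures and at 5082 ± 8147 and 3316 ± 3015 in heart captures, a difference of 3.68 (SE 0.88, adjusted p = 0.154). With AT3G15670 (0.20) it forms the measured part of the seed storage list, called higher with a median of 1.94 (adjusted p = 0.00367, and adjusted p = 0.0259 with an estimated correlation), with OLEO3 passing adjusted over the list alone. A wider list of 21 storage, oil body and late embryogenesis genes, OLEO3 among them, was not called (median -0.05, mean 0.09, 8 of 21 above 0, adjusted p = 0.12). Plastid-encoded genes had a median of 0.01 (adjusted p = 0.00409, and adjusted p = 0.154 with an estimated correlation); the call ended without heart cotyledon 3 (0.07, adjusted p = 0.0986) and without globular apical 3 (0.05, adjusted p = 0.0543), after quantile normalization (0.18, adjusted p = 0.137) and with the hybridization controls as a covariate (0.08, adjusted p = 0.0609).

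limma called 15 probe sets between heart and globular, 2 higher and 13 lower at the heart stage, and 5 carried a single gene name. Quantile normalization gave 6 higher and 13 lower, median centring 4 and 12, and array weights called 43, of which 19 were higher. The count was 50 without heart root 1, 37 and 25 without heart cotyledon 1 or 2, and 23 without globular basal 2; OLEO3 passed over all probe sets without heart root 1 (adjusted p = 0.0266) or heart cotyledon 2 (0.0471). By pole, 11 probe sets passed between heart cotyledon and globular apical, 1 higher and 10 lower, and 4 between heart root and globular basal, 1 higher and 3 lower. With array weights these were 18 higher and 13 lower, and 5 higher and 3 lower.

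Between the heart and torpedo stages, with cotyledon and root captures at both, CUL4, the scaffold of a ubiquitin ligase, fell from 1216 ± 1471 (SD, n = 3) and 1038 ± 482 (n = 3) to 12.2 ± 4.17 (n = 2) and 33.4 ± 18.24 (n = 2), a log2 difference of -4.80 (SE 0.87, adjusted p = 0.0467). That call was lost in 17 of 23 alternative runs, with adjusted p-values of 0.0192 to 0.81 over all of them; 6 of the 17 left out an array (heart cotyledon 1 or 3, heart root 1 or 3, torpedo cotyledon 3 or torpedo root 3), at 0.0538 to 0.148. AT3G62920 rose by 3.59, the rise lying in the cotyledon captures (6.45 between torpedo and heart cotyledon), and its arrays overlapped between stages, which places it outside the rule for named genes here; it lost its call in 17 of 23 runs as well. The remaining 2 calls were probe sets without a gene name. Type I MADS-box genes were higher at the torpedo stage (median 0.90, 20 of 21 members above 0, adjusted p = 0.00185) and cytosolic ribosomal protein genes lower (-0.45, 4.19e-06), at adjusted p = 0.518 and adjusted p = 0.531 with an estimated correlation. The MADS-box list was at 0.11 (adjusted p = 0.965) with the hybridization controls as a covariate and at 0.77 (adjusted p = 0.088) with the filter at 100%. The ribosomal list was at 0.39 (adjusted p = 0.738) without torpedo root 1 and at -0.21 (adjusted p = 0.134) after quantile normalization. The controls were 3156 to 71930 on these torpedo arrays and 581.6 to 3845 on the heart arrays.

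limma called 4 probe sets between torpedo and heart, 2 higher and 2 lower, against 2 and 1 after quantile normalization. The count was 224, 134, 20, 1 without torpedo cotyledon 1, root 1, cotyledon 3 and root 3, and 0, 141, 1 without heart cotyledon 1, 2 and 3, 2 and 0 without heart root 1 and 3, and 0 with array weights. By pole, 4 probe sets passed in cotyledon and 106 in root captures, against 0 in both with array weights. Over both poles 2029 probe sets were higher and 713 lower at the torpedo stage at an unadjusted p under 0.05.

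With torpedo apical and basal captures in place of cotyledon and root, a comparison added after seeing the data, 264 probe sets differed from the heart stage, 180 higher and 84 lower at the torpedo stage. The balance was 1038 higher and 1448 lower with array weights, 227 and 305 with a pseudocount of 1%, 124 and 34 after quantile normalization and 287 and 62 after median centring. The plastid-encoded photosystem II genes psbF (5.37, SE 1.22) and psbL (4.602, SE 1.14), the plastid ribosomal protein gene rps4 (4.23, SE 0.76), AT1G79150 (4.41, SE 0.55) and the ubiquitin-specific protease gene UBP23 (4.47, SE 0.71) rose. The photosystem I gene psaA (-2.61, SE 0.52) and AT1G53100 (-2.65, SE 0.45) fell. Of 68 plastid-encoded genes 7 passed upward and 1 downward, and the list rose with a median of 0.91 (adjusted p = 7.55e-10, and adjusted p = 0.00468 with an estimated correlation). Nuclear photosynthesis genes rose too (median 0.51, adjusted p = 1.28e-05, and adjusted p = 0.0215 with an estimated correlation). The photosynthesis (0.75), ribosomal (1.18) and cell division (0.23) lists were called higher, at adjusted p = 0.155, adjusted p = 0.309 and adjusted p = 0.177 with an estimated correlation. The ribosomal median was 0.44 without heart cotyledon 2, and the cell division list was at 0.11 (adjusted p = 0.185) with the controls as a covariate. psbF and psbL each lost their call in 9 of 12 runs with an array left out (adjusted p of 0.0507 to 0.0843 and 0.0694 to 0.116), while rps4, AT1G79150, UBP23, psaA and AT1G53100 passed in all 12; over 27 alternative runs psbF passed in 16, psbL in 14, psaA in 26 and the other 4 in all. The captures of the 2 stages differ in name, in the decimals of their deposited values and in the actin 3' to 5' ratio, which was 2.39 to 5.07 on the apical and basal arrays and -1.80 to 1.85 on the heart arrays. The count was 846, 137 and 98 without heart cotyledon 1, 2 or 3, 431, 94 and 143 without heart root 1, 2 or 3, 89, 857 and 78 without torpedo basal 4, 5 or 6, and 72, 105 and 93 without torpedo apical 4, 5 or 6.

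Whether the difference between poles itself changed with stage was tested as an interaction. From globular to heart limma called 0 probe sets, with 925 at an unadjusted p under 0.05 and 0 with array weights; the count was 1 without globular basal 3. From heart to torpedo it called 3, of which AT4G21110 had the largest value. Of the 3, 2 were higher and 1 lower, against 2 and 0 after quantile normalization or median centring. Its signal was 461 ± 755 in heart cotyledon, 7544 ± 5362 in heart root (SD, n = 3 each), 16340 ± 19731 in torpedo cotyledon and 8.85 ± 4.45 in torpedo root captures (n = 2 each), a difference of differences of 14.48 (SE 2.35, adjusted p = 0.0167). AT1G51610 went the other way, at 172 ± 24.7, 19.3 ± 7.09, 4.40 ± 1.27 and 205 ± 96.0 in the same order, -6.49 (SE 1.11, adjusted p = 0.0264). With each of 10 arrays left out in turn, AT4G21110 lost its call in 5 runs (adjusted p up to 0.127, without torpedo cotyledon 1) and AT1G51610 in 8 (up to 0.0925, also without torpedo cotyledon 1); over 23 alternative runs they lost it in 10 (adjusted p up to 0.231) and 15 (up to 0.256). The count was 127, 1 and 1 without heart cotyledon 1, 2 or 3, 8 without heart root 1, 0 and 16 without torpedo cotyledon 1 or 3, 1 and 0 without torpedo root 1 or 3, and 1 with array weights.

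The torpedo stage was captured under 2 sets of names, and the upper and lower captures were compared across them. Values of apical and basal captures were deposited unrounded and those of cotyledon and root captures with 1 decimal, so whether the 2 sets were processed alike is not known, and that bears on every difference between them. Against cotyledon captures, apical captures were higher in AT3G10040 (4.97, SE 0.75) and lower in AT5G45590 (-6.03, SE 1.03) and AT3G62920 (-5.78, SE 0.90). Without torpedo cotyledon 1 these 3 genes were at adjusted p-values of 0.0561, 0.0967 and 0.0734, and AT5G45590 also lost its call without each torpedo apical array (0.0537 to 0.0814) and AT3G62920 without torpedo apical 4 (0.0661). limma called 11 probe sets, 6 higher and 5 lower, with 4 and 2 after quantile normalization and 28 and 4 after median centring. Array weights called 34, of which 26 were higher and 8 lower. In the main fit 1453 were higher and 2652 lower in apical captures at an unadjusted p under 0.05. Plastid-encoded genes were called higher in apical captures (median 0.77, adjusted p = 6.15e-05, and adjusted p = 0.0873 with an estimated correlation). The cell cycle (median 3.11) and cell division lists (0.38) were called higher and type I MADS-box genes lower (-1.08), all at adjusted p = 0.0428, and at adjusted p = 0.317, 0.317 and 0.538 with an estimated correlation; these 3 calls ended without torpedo cotyledon 3 (0.737, 0.52 and 0.38, with the cell cycle median at 1.35) and without torpedo apical 4 (0.0754, 0.0754 and 0.0719). With the hybridization controls as a covariate the plastid-encoded list was at 0.61 (adjusted p = 0.0757), and the cell cycle, cell division and MADS-box lists at 0.04, 0.04 and -0.38 (all at adjusted p = 0.98). Over 21 alternative runs these 3 calls held in 10, 10 and 9. The cell cycle list holds only 3 measured genes of 37, AUR1, PRL and AUR2. All 3 are also in the cell division list, so its call is not separate from that of the cell division list. The actin 3' to 5' ratio was 3.71 to 5.07 on the apical arrays and 1.08 and 1.80 on the cotyledon arrays. The count was 4 and 42 without torpedo cotyledon 1 or 3, and 1, 3 and 6 without torpedo apical 4, 5 or 6.

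Basal captures were higher than root captures in plastid-encoded genes, with rps19 at 7.91 (SE 1.78), rps4 at 7.13 (SE 1.20), the intron maturase gene matK at 6.40 (SE 1.54) and psaB at 6.36 (SE 1.72). Of 68 such genes 8 rose and 0 fell, and of 63 cytosolic ribosomal protein genes 4 rose and 0 fell. UGT84B1, which glucosylates auxin (-4.30, SE 0.92), the osmotin-like gene OSM34 (-3.97, SE 0.66), the cytokinin response regulator ARR15 (-3.53) and the expansin gene EXPA24 (-2.84) were lower in basal captures. By camera plastid-encoded genes (median 0.88), cytosolic ribosomal protein genes (3.22), photosynthesis genes (3.09) and nuclear photosynthesis genes (1.29) rose, at adjusted p = 0.0031, 0.0247, 0.0183 and 0.00968 with an estimated correlation. In the photosynthesis list 4 of 9 genes passed adjusted over the list alone, and ATPC1, a subunit gene of the plastid ATP synthase (4.29), passed over all probe sets. Type I MADS-box genes (median -1.45, adjusted p = 0.00911) and the 5 measured endosperm genes (-2.16, adjusted p = 0.0402) were called lower in basal captures. With an estimated correlation they were at adjusted p = 0.261 and adjusted p = 0.188. AGL62 and AGL28 belong to both lists, so these calls are not separate results. Of the endosperm genes AGL62 (-2.64) and AGL28 (-2.42) passed adjusted over the list alone and 0 over all probe sets; without torpedo root 3 both lists lost their call (adjusted p = 0.126 and 0.244), and the endosperm list also did without torpedo basal 4 (0.0748) or 6 (0.0501). The root pole list (median 2.78, adjusted p = 0.0315) and the cell division list (0.28, 0.00837) were called higher, at adjusted p = 0.0882 and adjusted p = 0.133 with an estimated correlation, and without torpedo root 1 they were at 0.148 and 0.101. With the hybridization controls as a covariate the nuclear photosynthesis list was at 0.49 (adjusted p = 0.0964), the cell division list at -0.27 (0.964), the MADS-box list at -0.19 (0.8), the endosperm list at -0.77 (0.561) and the root pole list at 3.28 (0.0731). Over 19 alternative runs the MADS-box call held in 15, the cell division call in 14, the root pole call in 13 and the endosperm call in 11, and the ribosomal median was 1.32 without torpedo root 1.

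limma called 558 probe sets between basal and root, 92 higher and 466 lower in basal captures. The median log2 difference of all tested probe sets was -0.52, and after median centring 114 were higher and 94 lower, against 65 and 165 after quantile normalization, 17 and 140 with array weights, and 60 and 0 with only the groups compared in the fit. The actin 3' to 5' ratio was 2.39 to 4.64 on the basal arrays and -1.40 and -1.18 on the root arrays, and the 2 groups differ in the decimals of their deposited values. The count was 4 and 360 without torpedo root 3 or 1, 0 without torpedo basal 4 or 6 and 1455 without torpedo basal 5, and it was 0 with the hybridization controls as a covariate. rps4 and OSM34 lost their calls without torpedo root 3, basal 4 or basal 6 (adjusted p of 0.0617 to 0.0838 and 0.0617 to 0.0738). Over 18 alternative runs rps4 passed in 13, rps19, matK and OSM34 in 12, UGT84B1 in 9 and psaB in 8.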

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

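The tests of endosperm RNA in the globular captures and of weak heart arrays as sources of the falls at the heart stage were chosen only after the result was seen.

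6 results stood out because the difference between the cotyledon and root poles was not the same at the heart and torpedo stages. This came from a test of that difference itself. The 6 are not all separate, since all 9 measured photosynthesis genes also belong to the nuclear photosynthesis list. AT4G21110 differed by 14.48 (SE 2.35, adjusted p = 0.0167), with heart root above heart cotyledon and torpedo cotyledon above torpedo root on average. AT1G51610 differed by -6.49 (SE 1.11, adjusted p = 0.0264), with the reverse order at each stage. A probe set without a gene name differed by 9.61 (adjusted p = 0.00509). Photosynthesis genes had a median of 2.51 (adjusted p = 0.0238 with an estimated correlation), nuclear photosynthesis genes 0.90 (adjusted p = 0.0101 with an estimated correlation) and cytosolic ribosomal protein genes 4.29 (adjusted p = 0.0238 with an estimated correlation). Over 25 alternative runs these 3 medians ran from 1.56 to 4.64, 0.22 to 1.51 and 2.50 to 5.56, all past the threshold. AT4G21110 lost its call in 10 of 23 runs and AT1G51610 in 15. Each of these differences rests on the 2 torpedo root arrays, whose median correlations were 0.301 and 0.255, and on heart cotyledon 2, at 0.294. Without heart cotyledon 2 the photosynthesis list was at 2.96, the nuclear photosynthesis list at 0.49 and the ribosomal list at 3.33 in this difference, all past the threshold, although the ribosomal list of the heart stage alone was then at 0.0139 and the photosynthesis list at 0.30.

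Between torpedo basal and root captures, 466 probe sets were lower in basal. Weak hybridization of the torpedo root arrays could lift dim probe sets on them, and would then lift the same probe sets on heart cotyledon 2, another array of low correlation. Their median on that array was 0.92 above the other 2 heart cotyledon arrays (quartiles 0.28 to 1.60), against 0.63 for all tested probe sets, and this lay between the 2 values set beforehand, 1 or more for the explanation and 0.3 or less against it. Since all tested probe sets were raised by 0.63 on that array, a value of 0.3 or less was hardly within reach. The test therefore could not decide, and weak hybridization stays open. A difference between the basal and root captures as tissues stays open too, untested.

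Cytosolic ribosomal protein genes were lower in heart cotyledon than in heart root captures, with a median of -1.04. Without the arrays of low correlation, which at the heart stage means without heart cotyledon 2, the median was 0.0139 (quartiles -0.60 to 0.85), with 31 of 62 members above 0. That is the value which weak hybridization of a single array would need, and it may be the source of this difference. A difference between the poles was not tested apart from it.

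13 probe sets were lower at the heart than at the globular stage. Weak hybridization of heart arrays was tested only for heart cotyledon 2, the heart array of low correlation. Without the arrays of low correlation 12 of the 13 remained past the threshold in the same direction. Those 12 falls thus do not rest on that array, and weak hybridization of the other heart arrays stays untested. Endosperm RNA in the globular captures could give such falls, but the 5 measured endosperm genes had a median of -0.39 (from -0.95 to 0.10). The called probe sets had a median of -4.50. The endosperm median is far from the fall by 2 or more that the explanation was taken to need. It lies on the side set against the explanation (above -0.50), but beyond that bound by less than 0.19. That value is the standard error of the mean over the 5 genes, which holds no spread between arrays. The 5 genes were dim, with a highest mean signal of 149 in globular captures, and dim genes exclude nothing, so this explanation stays open. A change with stage in the embryo also stays open, untested.

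Other splits of the same arrays into groups of the same sizes were counted for 7 results. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. For globular the real count was 0 and the highest other 2, and for the difference of polarity between heart and globular they were 0 and 39; a real count of 0 is reached by every split, so these 2 counts test nothing. The real heart split called 2 and the highest other 42, with 4 of 10 splits calling as many, and the real torpedo apical and basal split called 19 and the highest other 1, with 1 of 10. For meristem against the other torpedo tissues chance cannot be excluded, with 1 probe set for the real split and 1035 for the highest other, and 23 of 100 splits called as many. For heart against globular chance cannot be excluded by this count either, with 15 and 42, and 7 of 100 splits. For torpedo against heart it cannot be excluded, with 4 and 1320, and 24 of 100 splits. For heart, meristem and torpedo against heart other splits called several times the real count, which points to some structure of the samples; which one was not tested, and single arrays that stand apart could give it too.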

How the results depend on the processing

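The tests without arrays of low correlation, without arrays of high hybridization controls, with those controls as a covariate, and with the 2 other torpedo groupings were chosen only after the result was seen. For named genes, 951 values under other settings kept their direction and side of the threshold, 234 lost their call and 14 gained one; with 1 array left out these were 401, 266 and 3. For gene lists 667 kept and 102 lost their call, and with 1 array left out 355 and 45. AT3G24510 and AT2G30810 between heart and globular and AT5G03350 in the meristem against 4 tissues passed under each alternative run. The labels do not say that a replicate number marks captures made together. Deviations of same-numbered arrays from their group means correlated at -0.09 to 0.06 in globular, -0.08 to 0.06 in torpedo apical and basal and 0.07 to 0.38 in heart captures. At the heart stage 5 of 6 arrays correlated best with their own number (the exception is heart root 3), and heart cotyledon 1 correlated at 0.822 with heart root 1 against 0.376 with its own group, so that shared numbers may mark related captures there; the replicate block left the heart count at 2. The small number of arrays and the spread of hybridization-control signal limit the precision of each count.

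For the 11 comparisons set beforehand, counts that moved by over 1.5 times follow; for each the cause was not tested. Quantile normalization gave 1 for torpedo cotyledon against root, 9 for apical against basal, 2 for meristem, 6 for apical against cotyledon and 230 for basal against root. Median centring gave 2 for torpedo against heart, 32 for apical against cotyledon and 208 for basal against root. A pseudocount of 1% gave 1 for cotyledon against root, 5 for apical against basal, 0 for torpedo against heart, 24 for apical against cotyledon and 212 for basal against root. A pseudocount of 50% gave 1 for globular, 109 for cotyledon against root, 30 for meristem, 67 for torpedo against heart, 32 for the torpedo and heart difference of polarity, 40 for apical against cotyledon and 1038 for basal against root. With no filter meristem gave 5, torpedo against heart 66, the torpedo and heart difference of polarity 5 and apical against cotyledon 19, and the filter at 100% gave 1 for torpedo against heart. With no trend cotyledon against root gave 5, apical against basal 7, torpedo against heart 1 and the torpedo and heart difference of polarity 20. Array weights gave 6 for heart, 0 for cotyledon against root, 196 for apical against basal, 43 for heart against globular, 0 for torpedo against heart, 1 for the torpedo and heart difference of polarity, 34 for apical against cotyledon and 157 for basal against root.

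Only the groups compared in the fit gave 1 for globular, 0 for heart, 0 for cotyledon against root, 5 for heart against globular, 0 for torpedo against heart, 0 for the torpedo and heart difference of polarity, 1715 for apical against cotyledon and 60 for basal against root, all of them higher against 92 higher and 466 lower before. The 2 contradicting arrays by title gave 1 for heart, 83 for cotyledon against root, 12 for meristem, 24 for heart against globular, 0 for torpedo against heart, 10 for the torpedo and heart difference of polarity, 5 for apical against cotyledon and 1141 for basal against root. By tissue they gave 0 for heart, 0 for cotyledon against root, 7 for apical against basal, 10 for meristem, 0 for torpedo against heart, 0 for the torpedo and heart difference of polarity, 493 for apical against cotyledon and 4 for basal against root. Without arrays of low correlation heart gave 7, heart against globular 26 and apical against cotyledon 134, and without arrays of high controls apical against cotyledon gave 39; both leave torpedo root with no array, so 5 comparisons could not be made. With the controls as a covariate heart gave 4, cotyledon against root 1, meristem 15, torpedo against heart 0, apical against cotyledon 0 and basal against root 0. A replicate block gave 1 for globular, 1 for cotyledon against root, 10 for apical against basal, 4 for meristem, 1 for torpedo against heart and 1 for the torpedo and heart difference of polarity. Meristem against apical and basal only gave 35, and torpedo apical and basal in place of cotyledon and root gave 264 against heart. The former count (35) moved to 12 after quantile normalization, 60 with a pseudocount of 50%, 572 with array weights, 64 with only the groups compared, 16 without arrays of low correlation, 14 without those of high controls and 1 with the covariate, and from 0 to 1409 with an array left out. The latter (264) moved to 158 after quantile normalization, 532 with a pseudocount of 1%, 2486 with array weights, 167 without arrays of low correlation and 66 with the covariate, and from 72 to 857 with an array left out.

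With each array left out in turn the counts ran from 0 to 2 for globular, 0 to 50 for heart, 0 to 86 for torpedo cotyledon against root, 3 to 17 for apical against basal, 1 to 56 for meristem, 14 to 50 for heart against globular, 0 to 224 for torpedo against heart, 0 to 1 and 0 to 127 for the heart and torpedo differences of polarity, 1 to 42 for apical against cotyledon and 0 to 1455 for basal against root. Where a group kept 1 array, that array was assumed to vary like the other groups. Direction changed as follows, and the cause was not tested. The plastid-encoded list in torpedo cotyledon against root was at -0.44 (adjusted p = 0.747) with the contradicting arrays by tissue. The ribosomal list at the heart stage was at 0.0139 without heart cotyledon 2 (range over arrays left out -1.53 to 0.0139) and at 0.0139 without arrays of low correlation, and YAB5 in torpedo apical against basal was at -0.19 without torpedo basal 6 (range -0.19 to 1.41). The median also changed sign, with the call lost, in 3 lists. The heart photosynthesis list was at 0.32 with array weights, 0.30 without heart cotyledon 2 or arrays of low correlation and 0.23 without heart root 3. The ribosomal list of torpedo against heart was at 0.39 without torpedo root 1, and the cell division list of basal against root at -0.27 with the covariate. 3 lists with a median near 0 took both signs over the settings, namely nuclear photosynthesis at the heart stage (-0.56 to 0.21) and plastid-encoded genes in heart against globular (-0.07 to 0.30) and in the torpedo and heart difference of polarity (-0.54 to 0.49).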

Other observations

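The comparison of torpedo root with heart root captures was set beforehand as a count, and the genes named and list tests given for it here were chosen only after the result was seen. Torpedo root captures were higher than heart root captures in UGT84B1, which glucosylates auxin (4.06, SE 0.92), the osmotin-like gene OSM34 (3.82, SE 0.66), the expansin gene EXPA24 (3.76, SE 0.77) and the auxin response repressor gene IAA18 (3.71), and lower in AT4G21110 (-8.32, SE 1.66). The median log2 difference of all tested probe sets was 0.51, so most differences in this comparison were positive. Of 106 probe sets past the threshold, 90 were higher and 16 lower at the torpedo stage, with 3750 at an unadjusted p under 0.05; with array weights limma called 0, with 2444 at an unadjusted p under 0.05. Of 40 expansin, xyloglucan and cellulase genes 37 had positive differences (median 1.06, adjusted p = 0.0203, and adjusted p = 0.393 with an estimated correlation). Of 19 auxin response and synthesis genes 16 did (median 1.22, adjusted p = 0.0443, and adjusted p = 0.293 with an estimated correlation). Both root pole genes had negative differences (median -2.96, adjusted p = 0.0394 with an estimated correlation). The 2 torpedo root arrays correlated with each other at 0.161. UGT84B1, OSM34 and EXPA24 were also named between basal and root captures. Both comparisons use these same 2 arrays, so they are not separate results. Signs of RNA quality and hybridization separated the groups completely: the actin 3' to 5' ratio was -1.40 and -1.18 on torpedo root and 0.44 to 1.49 on heart root arrays, and the hybridization controls were 9406 and 71930 against 725.9 to 3296. Apart from array weights and the estimated correlation no other setting was run for this comparison, so the differences named here were not separated from these array differences.

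2 arrays carried a title and a tissue description that name opposite torpedo tissues. The array titled cotyledon, with a root tissue description, had hybridization controls of 2018.55 and correlated on average at 0.764 with torpedo apical, 0.660 with torpedo basal, 0.528 with torpedo cotyledon and 0.289 with torpedo root arrays, against 0.539 to 0.667 with the globular and heart groups. Its highest correlation with a single array was 0.804, with heart cotyledon 1. The array titled root, with a cotyledon tissue description, had controls of 49046.5 and correlated at 0.245 with torpedo apical, 0.264 with torpedo basal, 0.337 with torpedo cotyledon and 0.255 with torpedo root arrays. Its highest group values were 0.353 with globular apical and 0.349 with globular basal, and its highest with a single array 0.368, with torpedo cotyledon 1, so these correlations do not settle which label is right.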
